A study of Sus scrofa with 12 samples.

How the data were processed

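Endometrial tissue of pregnant pigs was collected on days 12 and 15 of pregnancy, with 3 C/EBP-β ChIP libraries and 3 input samples per day. Per the labels' protocols, tissue was fixed with formaldehyde, chromatin was sonicated, and libraries were amplified and selected by size. Per the submitters' processing notes, Bowtie2 2.3.5.1, SAMtools 1.9 and MACS2 2.1.2 were used with the build susScr11. The calling threshold, the use of the input and any removal of duplicate reads are not given in the sources used here. Pooling of replicates is not stated either, and the peak names of each list name 1 library. The deposited files hold peak summits 1 bp wide. The score deposited by the authors with each summit is a −log10 of a p-value or q-value; which of them is not stated. Its lowest value was 2.02 in day 12 replicate 1 (a p-value or q-value of 0.00961) and 1.30 to 1.37 in the other 5 libraries. Scores grow with sequencing depth, so they were used only to rank or filter summits within a list, and days were compared by presence or absence. The files hold no read counts, so depth per sample is unknown, and no list gives an interval for it.

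Summits on the 18 autosomes, X and Y were analysed, 196220 of 198341. Coordinates were written counting from 1. Gene positions came from a RefSeq table of Sscrofa11.1, the assembly named susScr11 in the labels, which gives 30371 genes, 20663 of them protein-coding and 19550 of those on the chromosomes. It holds start and end without strand, exons or sequence, so the planned distance to a transcription start became the distance to either end of a gene. Location classes were reduced to within 2 kb of a gene end, inside a gene, and intergenic. The planned tests of 20 sequence motifs and a background matched on CpG content need the genome and were not run. A gene counted as having a summit when one lay within 5 kb of either end, and as bound on a day with 2 of 3 libraries. When a library of a day was left out, both others of that day had to have a summit, which is a stricter rule. For 67.6% of the genes another protein-coding gene lay within 10 kb, and the same summit can then count for both.

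Summits of any library within 200 bp were joined into regions. Chance was measured with 100 circular shifts of the summits of each library along the chromosomes. Numbers of summits, location shares, numbers of genes and log2 odds ratios (0.5 added to each cell) were compared between days with two-sided exact permutation tests, in which 3 against 3 libraries cannot give a p below 0.1. Gene lists were tested on each day with Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 46 tests and a threshold of 0.05. These tests treat genes, not samples, as units. The 23 lists held 549 entries, 530 of which matched the gene table by symbol or synonym. Intervals of shares are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

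The peak names showed 2 processing sets, with and without a directory path, and number codes that read as dates. There were 5 codes, 1 of them shared by day 15 replicates 2 and 3, and 0 shared between days. The sample part of the names of day 15 replicates 2 and 3 differs only in that the former names the protein. It does not name the protein in day 12 replicate 1 and day 15 replicate 3. The directory part of the names of day 12 replicate 1 does. Whether the list of day 15 replicate 3 comes from C/EBP-β ChIP therefore rests on the labels alone. Every comparison of single values between days was therefore repeated within the sets, with an exact permutation over the 9 arrangements that keep the sets (smallest p = 0.111).

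The gene lists, the tests and the rule for named genes were set before the data were examined, with distances to a transcription start in place of a gene end. The rule took all members of the C/EBP family, the nearest protein-coding gene within 50 kb of the 10 regions shared by all 6 libraries with the highest mean score percentile, and the same for 8 regions in each direction between days. From each list it took up to 4 members, first those differing by at least 2 libraries between days, then those bound in all 6 libraries, in alphabetical order. Some of the genes and regions that the rule names are not reported here.

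Alternatives planned beforehand were a score of at least 5 or 10, all sequences in the files, joining within 100 or 500 bp, equal numbers of the 6557 highest-scoring summits, gene ends within 1 or 5 kb for location, gene windows of 1 or 50 kb, all 3 libraries of a day, each replicate left out and a paired test by replicate number. Chosen after seeing the data were a score of at least 2, averaging within processing sets, a window of the gene body and 5 kb either side, 10000 random lists matched on gene length and neighbours, and the acute phase list without S100A9 and S100A12. The analysis was tested on simulated lists of the real lengths, run on 187458 regions. Of 1000 simulated regions shared by all 6 libraries 100% were recovered, of 200 regions of day 12 only 99% and of 200 of day 15 only 97%. On 19550 genes, lists of 25 members with an odds ratio of 8 were called in 98.8% of cases and with an odds ratio of 3 in 43.8%, against 0.278% and 0.556% of unchanged lists. Each simulated region had a summit in every library of its group, other summits were placed at random, and genes were drawn independently. Real summits cluster near gene ends and neighbouring genes share them. These rates therefore check the code and are not error rates for the real lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.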

Results

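Binding of C/EBP-β was mapped in pig endometrium, the lining of the uterus, on days 12 and 15 of pregnancy. C/EBP-β is a basic leucine zipper transcription factor encoded by CEBPB. In the pig, the conceptuses elongate and release oestrogen around day 12, and by day 15 they attach and secrete interferons. Chromatin was immunoprecipitated (ChIP) with an antibody against C/EBP-β and sequenced, and the peak names of each list name 1 library. The 6 ChIP libraries analysed comprised 3 of day 12 and 3 of day 15, and the 6 input samples were not analysed here. The labels do not say whether the 3 replicates of a day came from separate animals. The peak names of day 15 replicates 2 and 3 carry the same sample code. The permutation p-values therefore measure only the spread between these samples, which may be technical. Fisher's exact tests of gene lists and families take genes as units, so their p-values measure no spread between samples. The labels give the C/EBP-β antibody for all 6 libraries. The sample part of the peak names of day 12 replicate 1 and day 15 replicate 3 does not name the protein. For day 12 replicate 1 the directory part of the names does. Each list holds peak summits of 1 bp with a score given by the authors, and it holds no read counts, so sequencing depth is unknown. Coordinates are on the pig build susScr11.

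The lists differed widely in length within each day. On the assembled chromosomes, day 12 had 6557, 33294 and 57728 summits in replicates 1 to 3, and day 15 had 70152, 16529 and 11960. The mean log2 number was 14.51 ± 1.63 (SD, n = 3) on day 12 and 14.55 ± 1.36 (SD, n = 3) on day 15. The difference of 0.05, or 1.03-fold, was far below the spread between replicates (two-sided exact permutation p = 1, where 3 against 3 cannot go below 0.1). Its direction turned without day 12 replicate 1 (-0.87) and without day 15 replicate 1 (-0.73). The peak names divide the libraries into 2 processing sets, each with libraries of both days. Set A (names that carry a directory path) holds day 12 replicate 1 and day 15 replicates 2 and 3, and set B holds day 12 replicates 2 and 3 and day 15 replicate 1. Day 15 had 2.14-fold more summits than day 12 within set A and 1.60-fold more within set B (exact permutation within sets, p = 0.222, smallest possible 0.111).

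Summits lay near gene ends far more often than randomly shifted summits did. The annotation used gave the start and end of each gene without its strand, so either end of a protein-coding gene was counted. Within 2 kb of a gene end lay 34.2%, 17.3% and 17.0% of the day 12 summits and 20.1%, 45.1% and 48.8% of the day 15 summits, against 5.85% to 6.24% after circular shifts. The mean share was 22.9% ± 9.86 (SD, n = 3) on day 12 and 38.0% ± 15.6 (SD, n = 3) on day 15. The difference of 15.2 percentage points did not exceed what other divisions of the libraries gave (exact permutation p = 0.2, Benjamini-Hochberg adjusted 0.2 over 3 location classes). It was 9.78 points without day 15 replicate 3 and 24.1 points without day 15 replicate 1. The share inside genes was 41.3% ± 6.44 on day 12 and 33.7% ± 9.69 on day 15, and the intergenic share was 35.9% ± 3.42 and 28.2% ± 5.97 (SD, n = 3 each, exact permutation p = 0.2 for both). Within sets, the share near gene ends was higher on day 15 by 12.7 points in set A and by 2.96 points in set B (exact permutation within sets, p = 0.111). Set A as a whole had 42.7% ± 7.58 and set B 18.1% ± 1.72 of summits near gene ends (SD, n = 3 each, exact permutation p = 0.1).

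**Figure D1:**
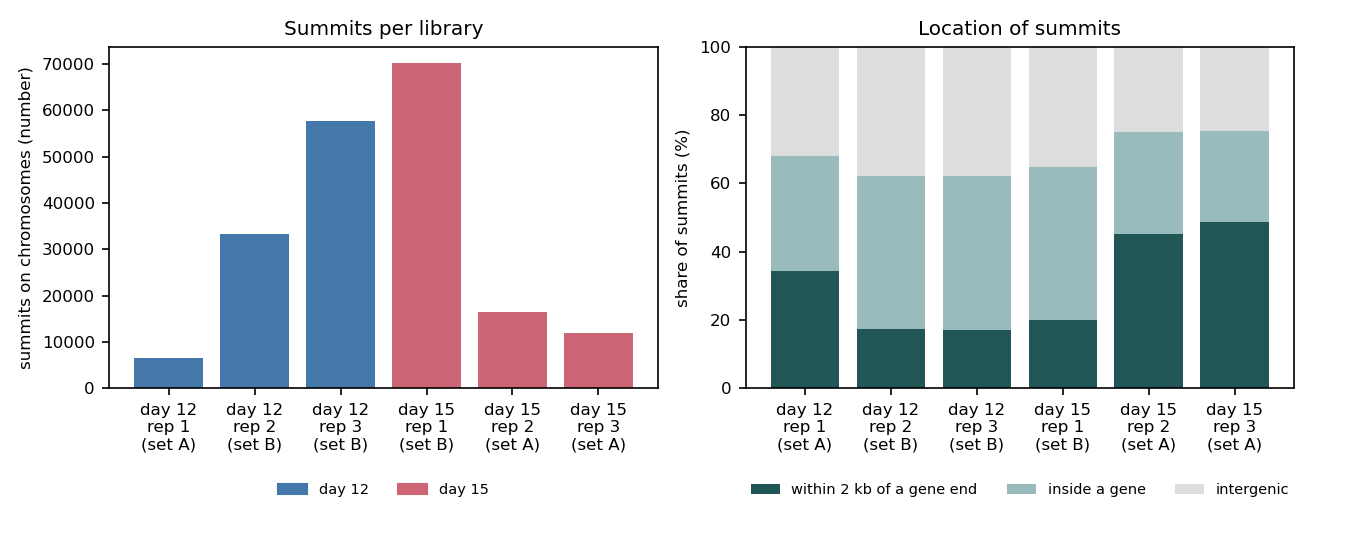
Number of summits on assembled chromosomes (left, bars coloured by day) and share of those summits in 3 location classes in percent (right) for each of the 6 libraries, with the processing set in brackets. List length ranges from 6557 to 70152 summits, and the share within 2 kb of a gene end is 34.2% to 48.8% in set A and 17.0% to 20.1% in set B.

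A core of regions was shared by every library of both days. Summits within 200 bp of each other were joined, which gave 99058 regions. Of these, 49983 (50.5%) came from 1 library and 2701 (2.73%) had a summit in all 6. None of 100 circular shifts gave any region shared by 6 libraries. The shifts moved each library independently and did not keep the placement of summits near gene ends, so this outcome was near certain. With the input not analysed and no motif tested, the sharing does not show that these regions are C/EBP-β sites. Among the shared regions, 38.9% lay within 2 kb of a gene end (95% exact binomial interval 37.1% to 40.8%), 31.4% inside genes and 29.7% in intergenic sequence. Without day 12 replicate 1, the shortest list, 4277 regions were shared by all remaining libraries. The 10 shared regions with the highest mean score percentile within the lists lay between percentiles 99.88 and 99.99. They included chromosome 6, 48406138 to 48406158, 89 bp from an end of PSMC4, which encodes a proteasome ATPase subunit. Further ones were chromosome 4, 93733813 to 93733844, 139 bp from CCT3, a chaperonin subunit gene, and chromosome 6, 4099258 to 4099314, 55 bp from COTL1, which encodes an actin-binding protein. The region next to QPCTL lay 139 bp from its nearer end, and that next to NAGK, the N-acetylglucosamine kinase gene, 829 bp. LMNTD1 had its region (chromosome 5, 48398926 to 48398934) inside the gene, 971 bp from an end. The regions nearest to PKIG, BZW2, AUH and LOC100627836 lay 5.8, 21, 11.8 and 10 kb from a gene end, those of PKIG and BZW2 inside the gene.

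Few regions separated the days completely. A summit in 3 of 3 libraries of day 12 and none of day 15 was found in 138 regions, and the opposite in 892. Only 15.2% of the day 12 regions lay within 2 kb of a gene end (95% exact binomial interval 9.67% to 22.3%), against 72.6% of the day 15 regions (69.6% to 75.5%). With the 6557 highest-scoring summits of each library, the counts were 419 and 142, and the shares near gene ends became 10.7% and 19.7%. Dividing the same libraries by processing set gave 12786 such regions, against 1030 by day, and with equal lists 1309 against 561. Single libraries moved the counts: the day 12 count became 4847 without day 12 replicate 1 and 1488 without day 15 replicate 1. The day 15 count became 2280 without day 12 replicate 3, and 1551, 1379 and 2138 without day 15 replicates 1, 2 and 3.

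The highest-ranked day 12 region lay in NFIL3, the gene of a bZIP repressor induced by interleukin 3 (chromosome 14, 2602673 to 2602689, 1.1 kb from a gene end). The 3 day 15 libraries had a summit elsewhere within 5 kb of an end of NFIL3. LPAR3, which encodes a lysophosphatidic acid receptor of the uterine epithelium with a role in embryo spacing, lay 6.8 kb from a day 12 region at chromosome 6, 128944540 to 128944611. Further day 12 regions lay 7.3 kb from HPS5, 21.3 kb from FBXL2 and inside ATG4C, an autophagy protease gene, 37.5 kb from its nearer end. The remaining 3 of the 8 had no protein-coding gene end within 50 kb. Of the 8, 6 held when summits within 500 bp were joined. Of the 8 day 15 regions, 7 lay within 2 kb of a gene end. CSTB (cystatin B, a protease inhibitor), WDR1 (an actin-disassembly protein) and TOGARAM1 had a summit within 5 kb of an end in 3 of 3 day 15 libraries and 0 of 3 day 12 libraries. Their regions were chromosome 13, 206710769 to 206710796, chromosome 8, 6452523 to 6452710, and chromosome 1, 175198225 to 175198322. CDC42, a small GTPase gene, TPD52L2 and LOC110261483 had day 15 regions within 0.2 kb of an end, but the 3 day 12 libraries had a summit elsewhere within 5 kb of an end of each. Another region lay inside LOC110257828 on chromosome X, 29.2 kb from its nearer end. Of the 8 day 15 regions, 3 held with lists of equal length, those of LOC110257828, TPD52L2 and CDC42, and 4 when summits within 500 bp were joined. The regions of CSTB, WDR1 and TOGARAM1 did not hold with lists of equal length but held with 500 bp.

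With all summits, libraries of the same day overlapped little more than libraries of different days. The mean Jaccard index of regions (shared regions divided by all regions of the pair) was higher within days by 0.0225 (one-sided exact permutation over 10 splits, p = 0.2). The difference turned negative without day 12 replicate 2 (-0.0069), without day 15 replicate 2 (-0.016) and without day 15 replicate 3 (-0.0152). Dividing the libraries by processing set gave 0.198. Within each set, the pair from the same day overlapped most, at 0.421 for day 12 replicates 2 and 3 and 0.421 for day 15 replicates 2 and 3, against 0.233 to 0.403 for the 4 pairs of different days. Across sets, the mean index was 0.142 for same-day pairs and 0.143 for different-day pairs. With equal lists these were 0.284 and 0.199, the difference between all same-day and different-day pairs was 0.0747 and that between sets 0.150. Day 12 replicate 1 then overlapped set B (mean index 0.334) more than the other libraries of set A (0.305). Day 15 replicates 2 and 3, which carry the same sample code, had 52 summits at identical positions, 0.435% of the shorter list.

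**Figure D2:**
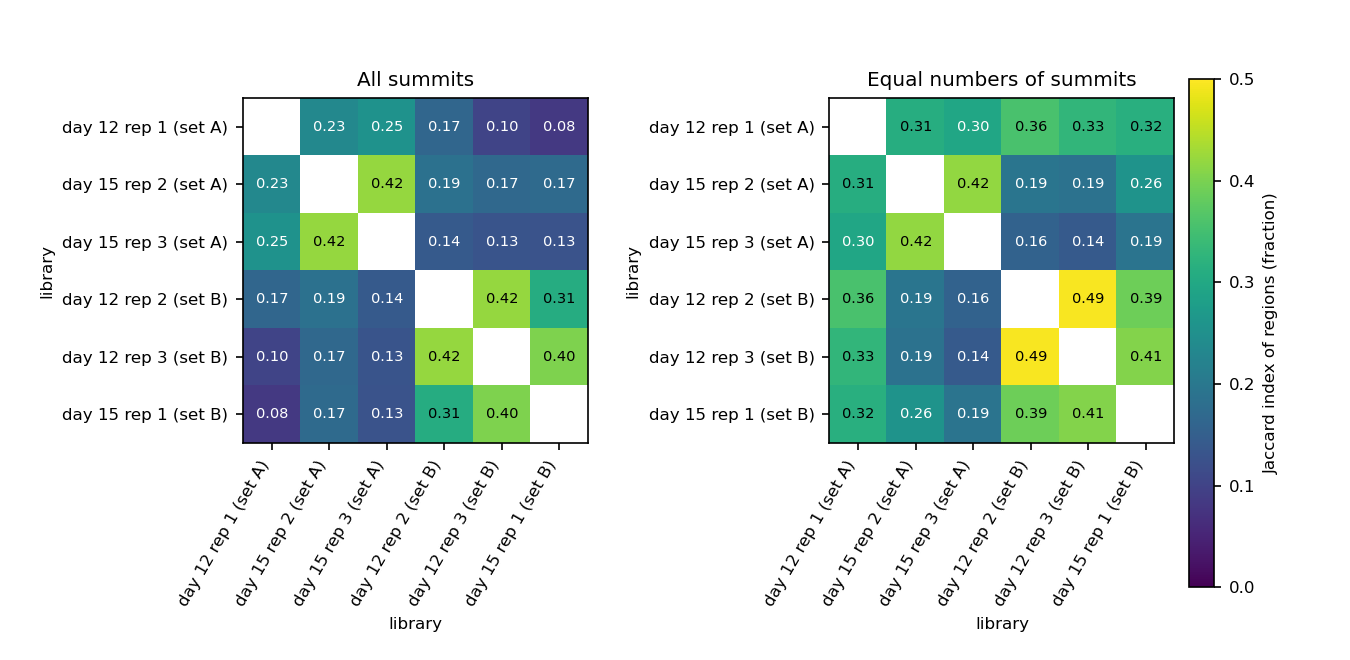
Jaccard index of the regions of each pair of libraries (colour and number, as a fraction; both axes list the 6 libraries in order of processing set) with all summits (left) and with the 6557 highest-scoring summits of each (right). The highest values are 0.421 for both same-day pairs within a set with all summits, and 0.495 for day 12 replicates 2 and 3 with equal lists.

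Among genes of the C/EBP family, CEBPB itself, CEBPG and DDIT3 (CHOP) had a summit within 5 kb of a gene end in all 6 libraries. CEBPD had one in 1 of 3 day 12 and 3 of 3 day 15 libraries. CEBPA and CEBPZ had one in 0 of 3 and 1 of 3, and CEBPE in 1 of 3 on each day. Of 19550 protein-coding genes, 7445 (38.1%) were bound on day 12, meaning a summit in at least 2 of 3 libraries, and 9042 (46.3%) on day 15. Both days shared 5958 bound genes, against 3443 for independent sets, and 2552 genes had a summit in all 6 libraries. Per library, day 12 had 3365, 7514 and 10586 genes and day 15 had 12669, 8724 and 7343. The mean log2 number differed by 0.53 (exact permutation p = 0.5), by 1.25 within set A and 0.51 within set B. Single libraries moved the 0.53, to 0.06 without day 12 replicate 1 and to 0.89 without day 12 replicate 3. These lists rest on different sets, since 4171 of the day 12 genes had no summit in the set A library of that day and 162 of the day 15 genes none in the set B library. The day 12 number was 3242 without day 12 replicate 2 and 2932 without day 12 replicate 3, and the number shared by both days 3089 and 2790. Both remaining day 12 libraries, the shortest list among them, then had to have a summit. With all 3 day 12 libraries required the day 12 number was 2900. A summit in 3 of 3 libraries of one day and none of the other was found for 6 genes of day 12 and 554 of day 15, and for 57 and 57 with equal lists. The day 12 number was 173 without day 12 replicate 1 and 140 without day 15 replicate 1, and the day 15 number was 1572 without day 12 replicate 3 and 912 without day 15 replicate 3.

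Immediate early, stress and cytokine signalling genes were bound more often than other genes on both days, and so were housekeeping genes. The other genes were all remaining protein-coding genes, whether expressed or not, and expression was not measured. Housekeeping genes had log2 odds ratios of 2.20 on day 12 and 3.11 on day 15. The calls therefore do not separate binding particular to these lists from binding at active genes in general. Of 23 gene lists, 9 differed from all other protein-coding genes on day 12 (7 bound more often, 2 less) and 9 on day 15 (5 more, 4 less), 6 of them on both days (Fisher's exact test, Benjamini-Hochberg adjusted over 46 tests). The day 12 number fell to 4 without day 12 replicate 2 and to 4 without replicate 3. The day 15 number was 8, 8 and 10 without day 15 replicates 1, 2 and 3. AP-1 and immediate early genes had 17 of 19 members bound on day 12 (log2 odds ratio 3.51, adjusted exact p = 7.9e-05) and 18 on day 15 (3.84, adjusted exact p = 0.00016), and 13 were bound in all 6 libraries, among them FOSB, FOSL2, EGR1 and DUSP1. Unfolded protein response genes had 17 and 20 of 22 (2.37, adjusted exact p = 0.00137, and 3.26, adjusted exact p = 0.00016). ATF4, the main factor of the integrated stress response, was bound in all 6 libraries, and EDEM1, SEL1L and EIF2AK3 in 1 of 3 and 3 of 3. IL6-JAK-STAT3 signalling had 16 of 25 members bound on day 12 (64%, adjusted exact p = 0.0301) and 23 on day 15 (92%, log2 odds ratio 3.45, adjusted exact p = 7.9e-05). The day 15 call held without day 15 replicate 1 and with a score of at least 5, at lower log2 odds ratios of 2.23 and 1.86. IL6ST, the shared receptor subunit of the IL6 family, and JAK1 had a summit in 1 of 3 day 12 and 3 of 3 day 15 libraries, TYK2 in 0 of 3 and 3 of 3, and BCL3 in 0 of 3 and 2 of 3. By the naming rule, members of each list that differed between days came first, so the named members do not stand for their list. The IL6-JAK-STAT3 call of day 12 was lost when a summit anywhere in the gene body also counted (0.99, adjusted exact p = 0.167). With a window of 50 kb, the neuronal call held on day 12 (adjusted exact p = 0.00275). On day 15 the interferon and unfolded protein response calls held (adjusted exact p = 0.000197 and 0.0363). No other call held. In that window 15643 genes were bound on day 12 and 14509 on day 15, of 19550, which leaves a list little room to exceed them. AP-1 genes kept log2 odds ratios of 3.29 and 3.76 on days 12 and 15, whereas those of housekeeping genes fell to 0.89 and 2.18.

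Interferon response and antigen presentation genes had 28 of 43 members bound on day 12 (65.1%, log2 odds ratio 1.58, adjusted exact p = 0.00189, Fisher's exact test) and 35 on day 15 (81.4%, 2.28, adjusted exact p = 7.9e-05). MX1, OAS2 (antiviral effectors) and SLA-DRA (an MHC class II chain) had a summit in 0 of 3 day 12 and 3 of 3 day 15 libraries, and BST2 in 1 of 3 and 3 of 3. The naming rule picked these genes for differing between days. Among all genes, 554 had a summit in 3 of 3 day 15 and 0 of 3 day 12 libraries, and 6 the reverse. With equal lists these numbers were 57 and 57. Without day 12 replicate 2 the interferon call of day 12 was lost (1.16, adjusted exact p = 0.0681). It was also lost without day 12 replicate 3 (1.17, adjusted exact p = 0.0893). Both remaining libraries, the shortest list among them, then had to have a summit. Losses of day 12 calls in these settings therefore cannot be ascribed to replicate 2 or 3 alone. With equal lists the day 12 log2 odds ratio of interferon genes was 0.42 (adjusted exact p = 0.732). Housekeeping genes had 15 and 18 of 20 members bound (2.20, adjusted exact p = 0.00364, and 3.11, adjusted exact p = 0.00046). ACTB was bound in all 6 libraries, SDHA in 1 of 3 and 3 of 3 and PGK1 in 0 of 3 and 2 of 3. Neuronal genes, a control list, had 1 and 3 of 23 (-3.21, adjusted exact p = 0.00177, and -2.34, adjusted exact p = 0.0043). The neuronal call on day 12 was lost without day 12 replicate 2 (adjusted exact p = 0.0681) or replicate 3 (adjusted exact p = 0.103), while the log2 odds ratio stayed at -3.23 and -3.05, and with equal lists (-2.33, adjusted exact p = 0.297). The housekeeping call on day 12 was lost with a score of at least 10 (1.46, adjusted exact p = 0.134) and a window of 1 kb (1.34, adjusted exact p = 0.105).

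On day 12, lipid and adipocyte genes had 18 of 25 members bound (log2 odds ratio 2.01, adjusted exact p = 0.00294) and cell cycle genes 17 of 27 (1.44, adjusted exact p = 0.026), and trophectoderm genes had 1 of 16 (-2.67, adjusted exact p = 0.0232). ADIPOQ, SCD (stearoyl-CoA desaturase) and SREBF2 were bound in all 6 libraries. APOE had 1 of 3 and 3 of 3, CCNE1 (cyclin E1) 3 of 3 and 1 of 3, and RB1 0 of 3 and 3 of 3. The lipid log2 odds ratio was -0.35 without day 12 replicate 2 and -0.18 without replicate 3, with a summit required in both remaining libraries. The other 2 calls were also lost without replicate 2 or 3, with log2 odds ratios of 1.13 and 1.05 for cell cycle genes (adjusted exact p = 0.201 and 0.189) and little changed ones of -2.72 and -2.54 for trophectoderm genes (adjusted exact p = 0.175 and 0.227). With equal lists the adjusted exact p was 0.818, 0.118 and 0.542 for lipid, cell cycle and trophectoderm genes. On day 15 they had 17 of 25, 18 of 27 and 3 of 16 members bound (adjusted exact p = 0.0891, 0.0985 and 0.0891). On day 15, acute phase and innate inflammation genes had 6 of 29 (-1.64, adjusted exact p = 0.0232), endothelial genes 1 of 14 (-2.95, adjusted exact p = 0.00834) and photoreceptor, lens and germ cell genes, another control list, 3 of 27 (-2.59, adjusted exact p = 0.00095). The acute phase and endothelial calls were lost without day 15 replicate 1 (-1.23 and -2.25, adjusted exact p = 0.109 and 0.102) and without day 15 replicate 2 (-1.34 and -2.36, adjusted exact p = 0.0776 and 0.0602). Here too a summit was required in both remaining libraries of the day. With equal lists the log2 odds ratios were -0.53 for acute phase genes, -1.20 for endothelial genes and -2.17 for photoreceptor, lens and germ cell genes (adjusted exact p = 0.647, 0.501 and 0.0965). On day 12 these lists had 16 of 29, 2 of 14 and 6 of 27 (adjusted exact p = 0.147, 0.158 and 0.178). CDH5, the endothelial cadherin gene, was the 1 endothelial member bound in all 6 libraries.

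The remaining lists did not pass on either day. Implantation and receptivity genes had 17 of 45 members bound on day 12 and 26 on day 15 (adjusted exact p = 1 and 0.207, Fisher's exact test). VEGFA (a vascular growth factor) and ITGB1 (integrin β1) had a summit in 0 of 3 and 3 of 3 libraries, HAND2 (a stromal progesterone-regulated factor) in 1 of 3 and 3 of 3, and BMPR2 in 0 of 3 and 2 of 3. Its 4 members bound on day 12 and not on day 15 were LPAR3 and the EGF-family ligands HBEGF, AREG and EREG, a group named after the values were seen, each with 2 of 3 and 1 of 3, and all 3 summits of each came from set B. Oestrogen and progesterone signalling genes had 11 and 13 of 25 (adjusted exact p = 0.694 and 0.857), with PGR (the progesterone receptor) in 1 of 3 and 3 of 3 and SULT1E1 (oestrogen sulfotransferase) in 3 of 3 and 1 of 3. Prostaglandin genes had 8 and 7 of 23 (adjusted exact p = 0.909 and 0.212), with PTGS2 (cyclooxygenase 2) and AKR1B1 in all 6 libraries and PTGER2 in 1 of 3 and 3 of 3. Nutrient and ion transport genes had 16 and 12 of 28 (adjusted exact p = 0.0985 and 0.909), with AQP9, ATP2B1, ATP2B4 and RBP4 in all 6. Extracellular matrix genes had 10 and 18 of 28 (adjusted exact p = 0.909 and 0.11), with ADAMTS1 and COL5A1 in 1 of 3 and 3 of 3. The C/EBP family as a list had 3 and 4 of 7 (adjusted exact p = 1 and 0.861).

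Markers of the cell types an endometrial sample could hold were also counted. Epithelial markers had 10 and 13 of 18 members bound (adjusted exact p = 0.212 and 0.0752), with KRT18 and CLDN4 in all 6 libraries and CLDN3 and CLDN7 in 1 of 3 and 3 of 3. Stromal fibroblast markers had 6 and 10 of 18 (adjusted exact p = 0.909 and 0.635), with PDGFRA in all 6 and COL1A1 and DCN in 1 of 3 and 3 of 3. Smooth muscle and pericyte markers had 5 and 9 of 14 (adjusted exact p = 1 and 0.267), with DES and LMOD1 in 0 of 3 and 3 of 3 and CNN1 in all 6. Myeloid markers had 7 and 6 of 17 (adjusted exact p = 0.909 and 0.633), with CD68, CSF3R, FCGR3A and ITGAM in all 6. T and NK cell markers had 2 and 4 of 17 (adjusted exact p = 0.0602 and 0.147), with LCK and NKG7 in 1 of 3 and 3 of 3.

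No list differed between the days after adjustment. The log2 odds ratio of list members against other genes was computed in each library and compared by an exact permutation test, and the lowest adjusted p was 0.575. In 4 of 23 lists the values of the 2 days did not overlap (exact permutation p = 0.1 each, the smallest possible), where chance gives 2.3. Interferon genes had 1.38 ± 0.27 on day 12 and 2.24 ± 0.36 on day 15, IL6-JAK-STAT3 genes 1.88 ± 0.51 and 2.79 ± 0.32, and housekeeping genes 2.01 ± 0.48 and 3.39 ± 0.97. Nutrient and ion transport genes had 0.96 ± 0.15 and 0.14 ± 0.24 (SD, n = 3 each). Within sets A and B the differences were 0.94 and 1.13 for interferon genes, 0.90 and 1.19 for IL6-JAK-STAT3 genes, 0.30 and 2.74 for housekeeping genes and -0.98 and -0.55 for transport genes. With equal lists, the differences between days were 0.60 for interferon, 0.37 for IL6-JAK-STAT3, 0.87 for housekeeping and -0.44 for transport genes. Those within set B were then -0.48, 0.11, 0.74 and 0.26. The lowest values under other settings were 0.05 for IL6-JAK-STAT3 genes with a score of at least 10 (exact permutation p = 1), 0.25 for interferon genes with a window of 1 kb (p = 0.4) and 0.45 for housekeeping genes with a score of at least 5 (p = 0.5). The number of lists without overlap was 13 without day 12 replicate 3 and 8 without day 15 replicate 1, where chance gives 4.6 with 1 library left out.

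Acute phase and innate inflammation genes had the most negative difference, -1.55, with 0.72 ± 0.41 on day 12 and -0.84 ± 1.12 on day 15 (SD, n = 3 each, exact permutation p = 0.2, adjusted 0.627). Members with a summit numbered 8, 16 and 17 in the day 12 libraries and 21, 6 and 5 in the day 15 libraries. The difference was -2.41 within set A and -0.15 within set B. By the rule of 2 in 3 libraries, 10 members were bound on day 12 and not on day 15, and 0 the other way. CSF3 (granulocyte colony-stimulating factor), HP (haptoglobin), S100A8 and S100A12 (calgranulins) had a summit in 3 of 3 day 12 libraries and 1 of 3 day 15 libraries. In each of these 4 genes the day 15 summit came from replicate 1. The windows of S100A12 and its neighbour S100A9 overlap, so that 1 summit can count for both. NFKBIA, PTX3 and SOD2 were bound in all 6 libraries.

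**Figure D3:**
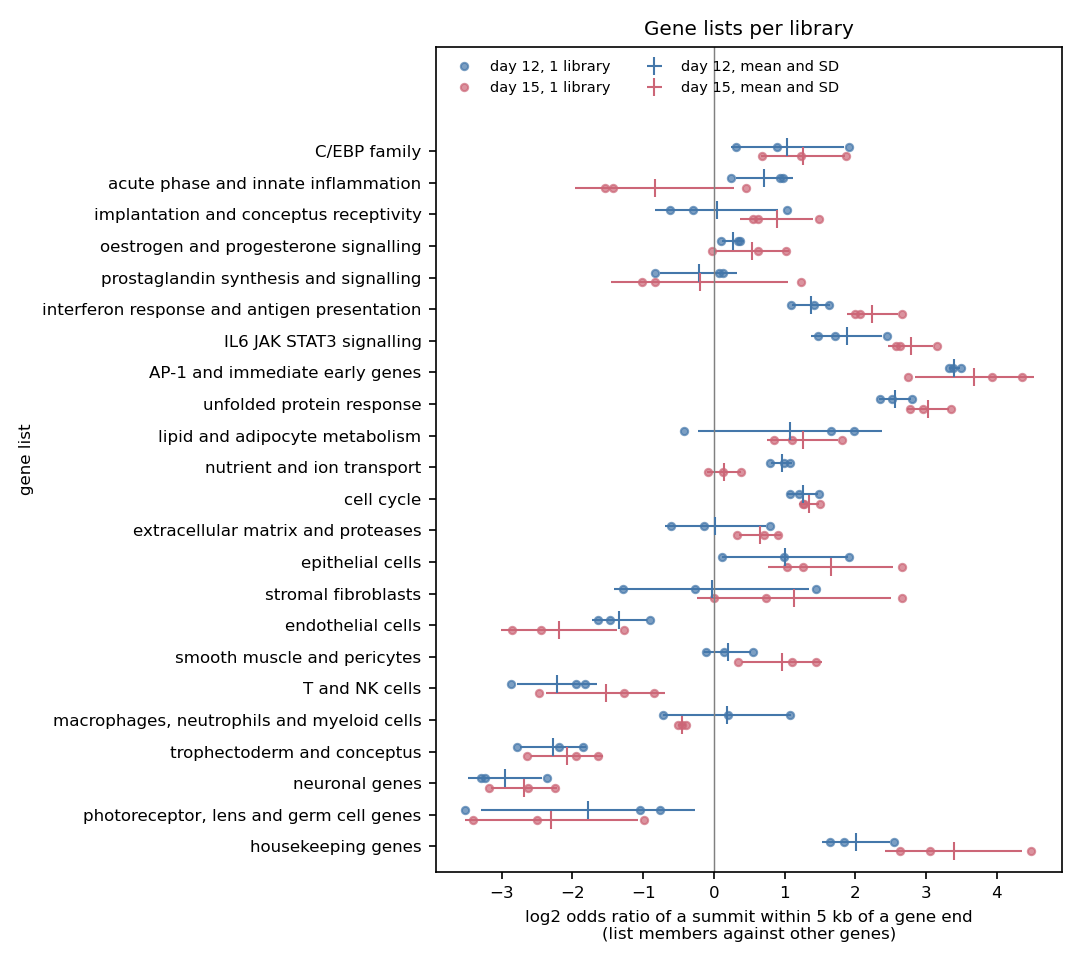
Log2 odds ratio of a summit within 5 kb of a gene end for members of each of 23 gene lists against all other protein-coding genes. Points are single libraries, and the bars give the mean and SD of the 3 libraries of a day. AP-1 and unfolded protein response genes lie above 0 in all 6 libraries, and acute phase genes lie at 0.72 ± 0.41 on day 12 and -0.84 ± 1.12 on day 15.

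**Figure D4:**
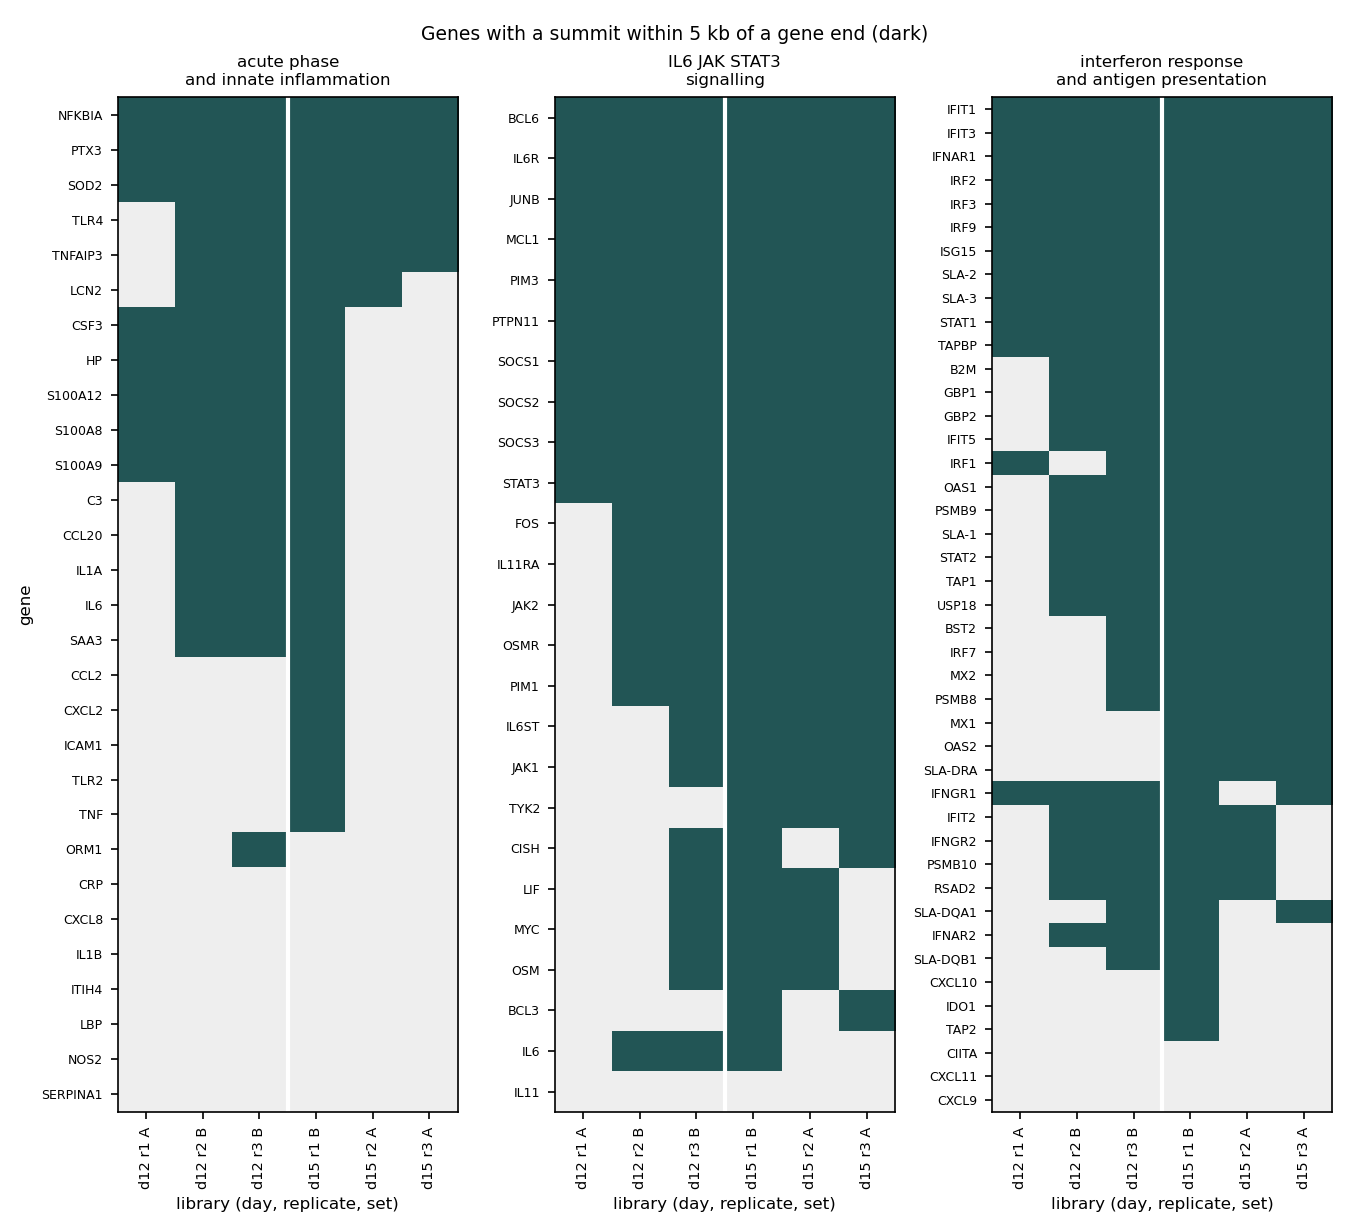
Presence (dark) or absence (light) of a summit within 5 kb of either end of each member of 3 gene lists (vertical axis) in the 6 libraries (horizontal axis, labelled by day, replicate and processing set). Of the acute phase genes, 21 are dark in day 15 replicate 1 and 6 and 5 in day 15 replicates 2 and 3.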

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

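All tests of explanations in this part were chosen after the results were seen. Summits outside the assembled chromosomes, a signal in data that the comparisons did not use, were present in every library. The 6 lists held 2121 of them on 158 unplaced scaffolds, 63 to 728 per library, and 454 lay on a single scaffold. Of these scaffolds, 13 had a summit in all 6 libraries and 51 in 1.

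Libraries of one processing set shared more regions than libraries of one day. List length is argued against as the whole cause, since with equal lists the split by set still gave the highest Jaccard difference of 10 splits, 0.150 against 0.0747 for the next, the split by day. A stricter score threshold in day 12 replicate 1 is also argued against as the whole cause. With a score of at least 2 in all libraries, the split by set still gave the highest difference, 0.198 against 0.0215 for the next. Without day 12 replicate 1, it gave the highest of the 10 splits into 2 and 3 libraries, 0.234 against 0.0661 for the next. That split does not decide the question. Set A then held only day 15 replicates 2 and 3, which share a day and a sample code and have the shortest lists left. A batch difference stays open: the share of summits near gene ends did not overlap between the sets, but 3 against 3 libraries allow no p below 0.1 (exact permutation p = 0.1), so this test does not decide. With equal lists day 12 replicate 1 overlapped set B (0.334) more than set A (0.305), whereas day 15 replicates 2 and 3, which share a sample code, overlapped set B at 0.188, so those 2 libraries may carry most of the division.

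The share of summits near gene ends was higher on day 15 within both sets, without passing a test. List length and unequal numbers of each set on the days cannot be told apart from gestation day, because each set has 1 library of one of the days and 9 arrangements allow no p below 0.111. The differences within sets A and B were 12.7 and 2.96 points, and 17.2 and 2.36 with equal lists (exact permutation p = 0.111 for both). Library date cannot be told apart from gestation day, because 0 date codes were shared by libraries of both days. Gestation day stays among the open explanations, as untested.

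Acute phase genes had a lower mean log2 odds ratio on day 15 (-1.55), without passing a test. One summit counted for several S100 genes is argued against as the cause, since without S100A9 and S100A12 the difference was -1.26, a move smaller than the SD of either day. List length and processing set cannot be told apart from gestation day here. With equal lists the difference was -1.38 but the days overlapped, and it was -2.41 within set A and -0.15 within set B (exact permutation within sets, p = 0.222). Day 15 replicates 2 and 3, which share a sample code, may therefore carry the difference, and a real change with gestation day stays open.

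The counts that separate the days were set beside all splits of the 6 libraries into 3 and 3, of which there are 10 with the split by day, too few for a share under 0.05. By day, 1030 regions had a summit in all libraries of one day and none of the other, and 3 of 10 splits, that by day included, gave as many, with 12786 by processing set as the highest. For genes the number was 560, 2 splits with that by day gave as many, and the highest other was 1151, again by processing set. The Jaccard difference by day was 0.0225, 2 splits with that by day gave as large a value, and the highest other was 0.198 by processing set. Set B holds the 3 longest lists, and 12712 of the 12786 regions were in set B only. With equal lists, 2 of 10 splits, that by day included, gave as many as the 561 regions and 114 genes by day, with 1309 regions and 1081 genes by processing set as the highest. A count several times that by day is a sign of a structure of the samples other than day, though these splits do not test it. Apart from the split by set, the highest others were 1186 regions, 469 genes and 0.0026 with all summits, and 161 regions, 40 genes and 0.0117 with equal lists.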

How the results depend on the processing

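Chosen after seeing the data were the score of at least 2, the mean within processing sets, the gene body window, the matched random lists and the acute phase list without S100A9 and S100A12; the other alternatives were planned. Of the values that answer a comparison, 52 moved and 5 reversed, the 5 with 1 library left out. The other 161 were counts of similar size or differences between days of the same direction, some at another size. Of single lists, 233 values kept direction and any call, 63 lost the call and 6 reversed. Differences between days could not pass the threshold with so few libraries, so they had no call to lose. Counts were judged singly. The turn from 138 regions of day 12 only and 892 of day 15 only to 419 and 142 with equal lists is thus among those that moved. Values of one day with a library of the other day left out are not counted, since they could not move. Except where a count has fewer summits, wider or narrower windows or fewer libraries by construction, the cause was not tested. The 20 motif tests, their alternatives and the background matched on CpG content were not run, and sequencing depth is unknown, so its effect on list length could not be tested.

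With a score of at least 5, 3887 genes were bound on both days. With a score of at least 10, regions of day 12 only, day 15 only and all 6 libraries numbered 38, 347 and 837, genes bound on day 12, day 15 and both 2738, 3967 and 1681, genes of day 12 only 1, and lists past the threshold on day 12 3. Joining within 100 bp gave 578 regions of day 15 only. Equal lists gave 419, 142 and 1047 regions, 1892, 3973 and 1391 genes, 57 genes of day 12 only, 57 of day 15 only and 5 lists on day 12. A gene window of 1 kb gave 4144 genes on day 12, 3541 on both days, 1 of day 12 only and 5 lists on day 12. A window of 50 kb gave 15643, 14509 and 13482 genes, 101 of day 15 only, 1 list on day 12, 2 on day 15 and 1 list whose days did not overlap. With all 3 libraries required, 2900 genes were bound on day 12, 2552 on both days, and 4 lists passed on day 12.

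With each replicate left out in turn, the log2 difference in summits ranged from -0.87 to 0.70, the Jaccard difference from -0.016 to 0.0904 and the share near gene ends from 9.78 to 24.1 points. Regions of day 12 only ranged from 151 to 4847, of day 15 only from 997 to 2280 and of all libraries from 2736 to 4277. Genes bound on day 12 ranged from 2932 to 7445, on day 15 from 6749 to 9042 and on both days from 2790 to 5747. Part of this range comes from the rule, since both remaining libraries of the shortened day had to have a summit. Genes of day 12 only ranged from 6 to 173 and of day 15 only from 624 to 1572. Lists past the threshold ranged from 4 to 9 on day 12 and from 8 to 10 on day 15, and lists whose days did not overlap from 4 to 13.

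Lipid genes on day 12 reversed with a 1 kb window (-0.0040), with all 3 libraries required (-0.16) and without day 12 replicate 2 (-0.35) or 3 (-0.18; 2.12 without replicate 1), endothelial genes on day 15 with a 50 kb window (0.19) and the difference between days of implantation genes with a 50 kb window (-0.42). Of the 12 alternatives that could move a list, the interferon and unfolded protein response calls of day 15 held in 12. The calls of AP-1 genes on either day, unfolded protein response genes on day 12 and IL6-JAK-STAT3, neuronal and housekeeping genes on day 15 held in 11. Those of IL6-JAK-STAT3 genes on day 12 and photoreceptor, lens and germ cell genes on day 15 held in 10, of housekeeping genes on day 12 in 9, and of neuronal genes on day 12 in 6. Interferon and lipid genes on day 12 held in 5, endothelial genes on day 15 in 4, and cell cycle and trophectoderm genes on day 12 in 3. The acute phase call of day 15 held in 4 of 13.

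Replicate numbers gave no clear sign of pairing. The correlations of same-number libraries were 0.0633, -0.0521 and 0.130, against -0.149 to 0.105 for libraries of different numbers. So few values cannot show how the samples were collected. With the replicate number as a block, the mean differences equal the unpaired ones by construction. They were 0.05 for log2 summits (exact sign-flip permutation p = 1), 15.2 points for the share near gene ends (p = 0.5) and 0.53 for the log2 number of genes (p = 0.75). The smallest possible p is 0.25, so no call could arise.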

Other observations

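The gene families in this part, with their tests, and the counts on the Y chromosome were chosen after the results of the gene lists had been seen. Genes of protein synthesis, proteasomes and respiration, of which the gene lists held few, were bound more often than other genes on day 15. Of 77 genes of cytosolic ribosomal proteins, 3 of them also in the housekeeping list, 45 were bound on day 12 and 70 on day 15, against 38.0% and 46.1% of other genes. Their log2 odds ratio was 1.19 on day 12 and 3.46 on day 15 (Fisher's exact test, adjusted p = 0.00091 and 3.3e-15, over 18 tests). In single libraries 27, 46 and 59 of them had a summit on day 12 and 75, 68 and 64 on day 15. Mitochondrial ribosomal proteins had 37 and 59 of 74 (adjusted exact p = 0.0522 and 3.3e-08), proteasome subunits 20 and 31 of 39 (0.112 and 9.5e-05) and subunits of respiratory complex I 21 and 27 of 37 (0.0365 and 0.00278). The difference between days was not tested for these families, and day 12 and day 15 hold unequal numbers of libraries of each processing set.

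Keratins and cadherins were bound less often than other genes on both days. Of 35 keratin genes, 6 were bound on day 12 and 1 on day 15 (log2 odds ratio -1.48, adjusted exact p = 0.022, and -4.31, adjusted exact p = 4.6e-08). Of 35 cadherin and protocadherin genes, 4 and 1 were bound (-2.11, adjusted exact p = 0.00162, and -4.31, adjusted exact p = 4.6e-08). Genes of both families lie in clusters, so their members are not independent. Zinc finger genes named ZNF had 115 and 167 of 254 members bound (adjusted exact p = 0.0287 and 3.1e-09), solute carriers 141 and 137 of 348 (0.365 and 0.0192) and homeobox cluster genes 16 and 23 of 36 (0.493 and 0.0522).

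Endometrium is a female tissue, and the lists held 118 summits on the Y chromosome, 0.0595% of all summits. Their origin was not tested, and sequence shared with X was not set apart. They formed 64 regions, 39 of them in 1 library and 8 in at least 4 libraries, the 8 between positions 3369067 and 6996335. The highest score among the summits on Y was 89.8.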
